A study of Homo sapiens with 6 samples.

How the data were processed

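Exosomes were obtained from about 250 mL of conditioned medium of THP-1 macrophages or M2 macrophages, kept in serum-free medium for 30 h, by precipitation, ultrafiltration and ultracentrifugation, per the labels' protocols. The preceding culture used serum depleted of exosomes. From 30 ng of RNA, adapters were ligated to both ends and the cDNA was amplified and sequenced on an Illumina NovaSeq system, per the labels' protocols. No molecular identifiers are named there, so intervals and floors cover counting error only. The authors deposited 1 table with raw read counts and TPM values of 656 miRNAs, 46 of them unannotated candidates, in each of the 6 libraries. The deposited TPM values are the counts divided by the column total and scaled to a fixed sum, per the file headers and a check of the values (largest difference 4.66e-10). The submitters' processing notes name DESeq and R 4.2.2 without a role. The aligner, the miRNA annotation, the genome build and the rule for reads that match several miRNAs are not given in the sources used here.

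Columns were assigned to libraries by their names, in which the macrophage columns are called control and the M2 columns carry TGF and a replicate number. The M2 stimulus was given in the labels as 20 ng/mL of IL-4 and of IL-13 or as TGF-β, for 48 h, and the cell type label names M2-like monocytes for M2 replicates 2 and 3 and M2-like macrophages for replicate 1. Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM factors, filterByExpr with a minimum count of 10), for M2 minus macrophage exosomes. Adjusted p-values are Benjamini-Hochberg values over the 181 miRNAs that passed the filter, with a threshold of 0.05. Levels are CPM from TMM-scaled library sizes. Log2 changes carry the standard error that the F statistic implies. A miRNA with no count in a group is given as a bound against 3 counts over that group, and one with 1 to 3 counts as a ratio with its exact 95% interval. The bound leaves out the counting error of the other group, so it is not a 95% limit. The TMM factors ranged from 0.532 in M2 replicate 3 to 1.33 in macrophage replicate 2.

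Named miRNAs were fixed by rule before the data were examined. They were up to 12 in each direction with the largest change among those called, with groups that did not overlap and a mean of at least 50 CPM in the higher group, the 10 most abundant, 12 chosen from macrophage and exosome biology, and up to 4 per list. The 29 lists, also fixed before the data were examined, cover macrophage activation, NF-κB and TGF-β responses, myeloid identity, published M2 exosome cargo, prostate cancer, miRNA families and clusters, hypoxia, red cells and serum, other cell types and fragments of other RNAs. Lists with 3 or more tested members were tested with camera (limma 3.58.1, preset correlation 0.01). The alternatives were RLE and upper-quartile factors, total counts alone, no filter, a minimum count of 50, DESeq2 1.42.0, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 10), the 5 most abundant miRNAs left out, a replicate block and each replicate left out.

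Macrophage replicates 2 and 3 were close to sampling noise (chi-square per degree of freedom 1.34, p = 0.00384, over 148 miRNAs), while replicates 1 and 2 gave 7.60 and M2 replicates 1 and 2 gave 24.2. They still differed by more than counting noise and were kept as separate libraries. M2 replicate 3 was far from M2 replicates 1 and 2 (468 and 436). These values grow with the counts of the libraries compared, so pairs of unlike depth cannot be read as distances on 1 scale. With every library thinned to 56199 counts, the median distance of M2 replicate 3 from the other M2 libraries was 2.66 times theirs from each other. A principal component with 61.6% of the variance separated the groups, and a component with 28.2% separated M2 replicate 3 from M2 replicates 1 and 2. Hairpins that overlap on opposite strands in GENCODE 29, or names with equal counts in every library, were listed as sharing reads. Examples are miR-24-3p with miR-3074-5p (9178 and 9171 counts) and miR-423-5p with miR-3184-3p (16595 each). The calls were tested on simulated data with the libraries' own depths and spread. Of miRNAs changed 2-, 4- and 8-fold, 5.75%, 31% and 68% were recovered in 20 draws with 181 miRNAs, and 3.83% of calls were wrong. The simulated rises and falls were equal in number and each miRNA was drawn independently. The share of wrong calls therefore does not cover errors of the scaling or a set of miRNAs raised together in 1 library. The list test called the list of prostate cancer promoters (11 tested members) in 20 of 20 draws with every member raised 4-fold in otherwise unchanged data. Smaller lists, partly changed lists and members that vary together were not simulated, so this does not show that such lists would be found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.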

Results

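Small RNAs were sequenced from exosomes, the small vesicles that cells release into their medium, of THP-1 cells, an established human monocytic leukaemia line. THP-1 cells become macrophages under phorbol ester (PMA), here at 100 ng/mL for 48 h, and a further stimulus polarises macrophages to the alternatively activated state called M2. The series' design text names TGF-β as that stimulus, and the table's columns for the M2 libraries carry its name, whereas the sample labels leave open IL-4 with IL-13 or TGF-β. There were 3 libraries of exosomes from macrophages and 3 of exosomes from M2 macrophages. The M2 stimulus lasted 48 h, and no matching time without it is recorded here for macrophages. Time in culture after PMA may therefore differ between the groups along with polarisation. The question stated in the series' design was how the exosomal miRNAs of M2 macrophages differ from those of macrophages, in the setting of prostate cancer. Total miRNA counts were 73566, 56199 and 76728 in macrophage replicates 1, 2 and 3, and 102912, 126844 and 383577 in M2 replicates 1, 2 and 3. A count of 0 therefore allowed a level of up to 40.4 CPM (counts scaled to TMM-adjusted library totals) in the shallowest library and 14.9 CPM in the deepest. Nothing in the labels says that replicates came from separate cultures, so that p-values measure only the spread between these libraries, which may be technical.

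A small number of miRNAs made up most of the exosomal cargo in both groups. The 10 most abundant held 65.2% ± 1.26 of the counts in macrophage exosomes and 67.1% ± 6.22 in M2 exosomes (SD, n = 3 each; two-sided exact permutation p = 0.9, where the smallest possible is 0.1). The leading miRNA was miR-148a-3p in the 3 macrophage libraries and miR-21-5p in M2 replicates 1 and 2. In M2 replicate 3 it was miR-10b-5p, with 29.7% of the counts, against 0.181% and 2.32% in M2 replicates 1 and 2. At least 10 counts were found for 158 ± 10.0 miRNAs per macrophage library and 227 ± 52.2 per M2 library (SD, n = 3 each; exact permutation p = 0.1). With every library thinned to 56199 counts these became 143 ± 9.29 and 145 ± 2.52 (exact permutation p = 0.9), so no difference in the number of miRNAs was detectable at equal depth.

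Exosomes of M2 macrophages held more miR-320a-3p, miR-146a-5p, miR-221-3p, miR-22-3p, miR-378a-3p and miR-23a-3p than exosomes of macrophages, and less miR-148a-3p, let-7b-5p, let-7d-3p, miR-451a and miR-4488. Of 181 miRNAs tested, 70 differed (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 51 of them higher and 19 lower in M2 exosomes. Of these, 66 changed at least 2-fold, 50 higher and 16 lower. With TMM-scaled levels the groups did not overlap for 113 of the 181 tested, where chance gives 10% for any 1 miRNA. A shift shared by all miRNAs can raise that count, which was not taken under other scalings. The balance of rises and falls depended on the scaling: 42 rose and 36 fell with RLE factors, 42 and 26 with upper-quartile factors, 28 and 29 with total counts alone, and 45 and 39 in DESeq2. The median log2 change of all tested miRNAs was 0.95 with the TMM factors used throughout, 0.40 with RLE, 0.39 with upper-quartile and 0.07 with total counts, so changes below are best read against a shift of 0.95. Without macrophage replicate 2 or 3 the log2 changes moved by a median of -0.73 or -0.77 (median of all tested 0.14 or 0.01), and without M2 replicate 2 by -0.34. With M2 replicate 3 left out, they moved by a median of 0.08 (median of all tested 0.62), so changes from that fit are best read against 0.62. Under all 4 factor methods and DESeq2, 47 miRNAs were called in the same direction, 28 higher and 19 lower. Without macrophage replicate 2 the count of differing miRNAs was 35, without macrophage replicate 3 it was 37, without M2 replicate 2 it was 37, and without M2 replicate 3 it was 116.

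**Figure D1:**
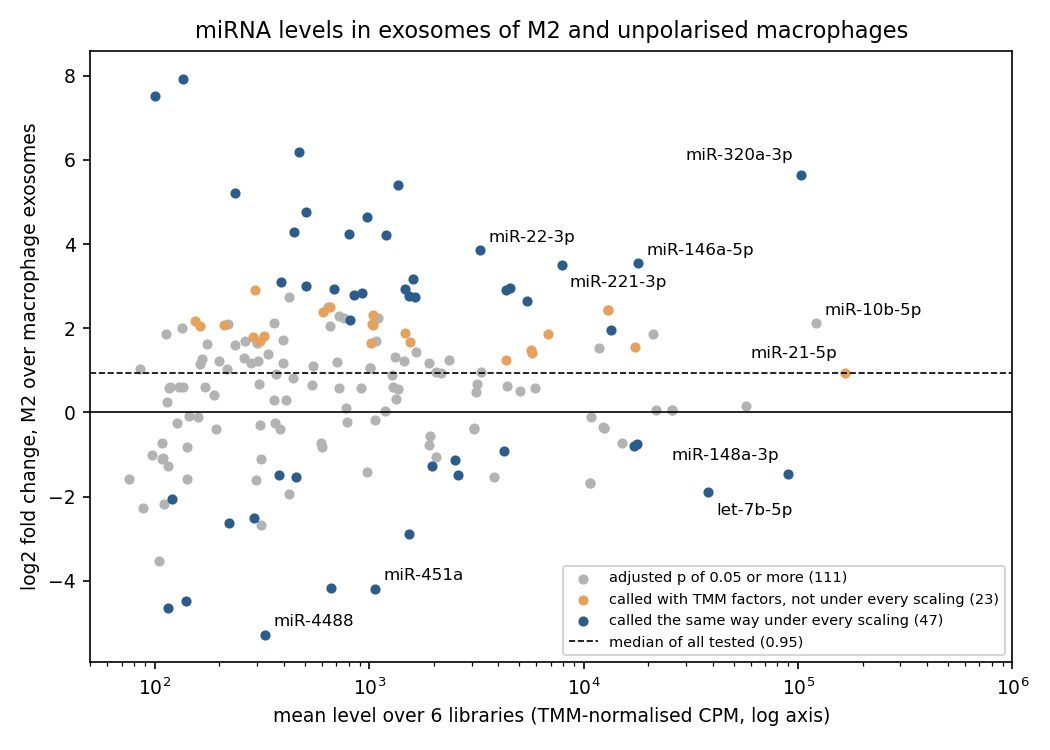
Log2 fold change of M2 over macrophage exosomes (vertical axis) against the mean level over the 6 libraries (TMM-normalised CPM, log axis) for the 181 tested miRNAs, 1 point each. The 47 blue points were called in the same direction under every scaling, orange points were called with TMM factors only or under some scalings, grey points were not called, and the dashed line marks the median change of 0.95.

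Among the rises called in every alternative, the most abundant was miR-320a-3p, which went from 4062 ± 151 to 203369 ± 149148 CPM (SD, n = 3 each), a log2 change of 5.65 ± 0.63 (SE; edgeR adjusted p = 0.00162). Its M2 libraries held 94935, 141712 and 373460 CPM. miR-146a-5p, an NF-κB-induced regulator of inflammatory signalling, rose from 2828 ± 184 to 32984 ± 6745 CPM (log2 3.54 ± 0.23, adjusted p = 0.000488). miR-221-3p rose from 1269 ± 281 to 14510 ± 3058 CPM (log2 3.51 ± 0.29, adjusted p = 0.00100). miR-22-3p rose from 425 ± 30.9 to 6174 ± 580 CPM (log2 3.86 ± 0.22, adjusted p = 0.000420). At lower levels, miR-26b-5p rose by a log2 of 4.76 ± 0.69, miR-378c by 4.65 ± 0.56, miR-378d by 4.29 ± 0.55 and miR-99b-3p by 4.25 ± 0.40. miR-378c and miR-378d are near-identical to other members of their family, so their separate values are uncertain. These 8 were called in every alternative in which they were tested, although without M2 replicate 3 the log2 changes of miR-320a-3p and miR-26b-5p were 5.00 and 4.16. miR-1269b and miR-6515-5p had no count in any macrophage library and 113 and 88 counts over the M2 libraries, and were at least 23.0-fold and 17.9-fold higher against 3 counts over the macrophage group (12.7-fold and 9.88-fold with total counts alone). The lower ends of their exact 95% counting intervals, which include the counting error of the M2 counts, were 18.4-fold and 14.3-fold. miR-29b-3p and miR-629-5p had 3 counts each in the macrophage group, with ratios of 97.0 (95% counting interval 33.0 to 472) and 43.0 (14.5 to 210). With total counts alone these ratios were 53.4 and 23.7, and without M2 replicate 3 that of miR-29b-3p was 42.7. miR-193a-5p rose by a log2 of 5.40 ± 1.09 and miR-20a-5p by 4.22 ± 0.91 (3.07 without M2 replicate 3). Without macrophage replicate 2 the calls of miR-29b-3p, miR-629-5p, miR-193a-5p and miR-20a-5p ended (adjusted p = 0.0633, 0.0634, 0.0637 and 0.0805), as did those of miR-629-5p and miR-20a-5p without macrophage replicate 3 (0.0560 and 0.0757) or with macrophage replicates 2 and 3 added up (0.0612 and 0.0622), and that of miR-20a-5p in limma-voom (0.0697).

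Among the falls, miR-148a-3p, the leading miRNA of macrophage exosomes, went from 131634 ± 6943 to 47592 ± 7316 CPM (SD, n = 3 each; log2 -1.47 ± 0.20 SE, edgeR adjusted p = 0.00316). let-7b-5p went from 59952 ± 3807 to 16218 ± 2450 CPM (log2 -1.89 ± 0.20, adjusted p = 0.00127). let-7d-3p, the passenger arm of its hairpin, went from 2689 ± 295 to 362 ± 153 CPM (log2 -2.89 ± 0.40, adjusted p = 0.00316). miR-451a, abundant in red blood cells, went from 2025 ± 360 to 110 ± 71.1 CPM (log2 -4.19 ± 0.60, adjusted p = 0.00352). miR-4488 went from 640 ± 31.3 to 14.4 ± 9.05 CPM (log2 -5.28 ± 0.53, adjusted p = 0.00119), on 165 counts against 7. These 5 were called in every alternative in which they were tested. miR-3614-5p was read 58 times in the macrophage group and 3 times in the M2 group, a ratio of 0.0316 (95% counting interval 0.00634 to 0.0971), which was 0.0174 with total counts alone and 0.0669 without M2 replicate 3. The other falls chosen by the same rule were miR-4466 (log2 -4.48), miR-130b-5p (-4.16), miR-2682-5p (-2.64), the unannotated candidate novel_345 (-2.52), miR-409-3p (-2.05), miR-223-5p (-1.53) and let-7c-5p (-1.49). Without M2 replicate 3 the log2 changes of miR-4466, miR-130b-5p, miR-2682-5p and miR-409-3p were -3.64, -5.90, -2.00 and -2.65. With macrophage replicates 2 and 3 added up, the calls of these 7 and of miR-3614-5p ended (edgeR adjusted p from 0.0622 to 0.104), and all but miR-223-5p also lost the call without at least 1 library. Without macrophage replicate 1 this held for miR-130b-5p, miR-2682-5p, miR-409-3p and let-7c-5p (adjusted p from 0.0525 to 0.0636). Without macrophage replicate 2 or 3 it held for miR-3614-5p, miR-130b-5p, miR-2682-5p, novel_345 and miR-409-3p (0.0529 to 0.0634 and 0.0544 to 0.0595). Without M2 replicate 1 it held for miR-3614-5p, miR-2682-5p, miR-409-3p and let-7c-5p (0.0514 to 0.103), and without M2 replicate 2 for miR-4466, miR-130b-5p, miR-2682-5p, novel_345 and miR-409-3p (0.0592 to 0.0991).

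**Figure D2:**
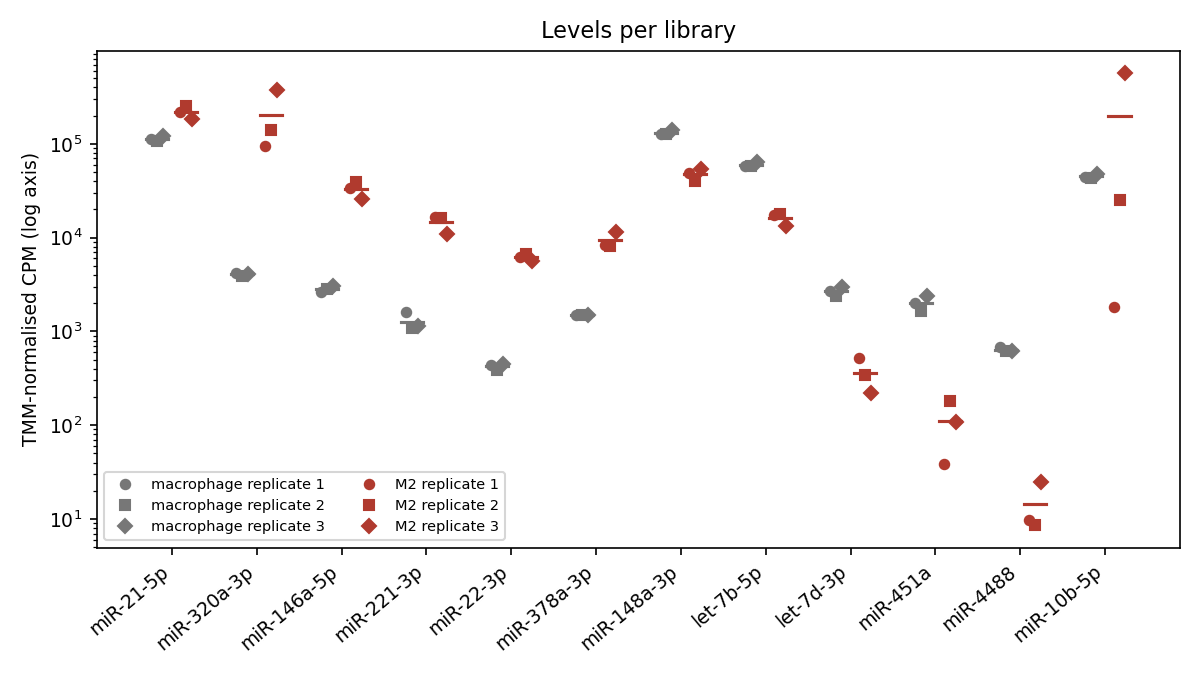
Level of 12 miRNAs in each library (TMM-normalised CPM, log axis), with macrophage exosomes in grey and M2 exosomes in red, marker shape for the replicate and a bar for the group mean. miR-320a-3p, miR-146a-5p, miR-221-3p, miR-22-3p and miR-378a-3p lie higher in every M2 library, and miR-10b-5p spans 1803 to 564574 CPM within the M2 libraries.

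Other abundant miRNAs differed less or varied more. miR-21-5p, a widely expressed miRNA often raised in tumours and activated macrophages, was at 113561 ± 7054 CPM in macrophage and 218642 ± 33696 CPM in M2 exosomes (SD, n = 3 each; log2 0.95 ± 0.20 SE, edgeR adjusted p = 0.0144). That change equals the median shift of all tested miRNAs, and the call ended with RLE, upper-quartile and total-count scaling (adjusted p = 0.244, 0.284 and 0.558) and without macrophage replicate 1, 2 or 3 or M2 replicate 2 (0.0786, 0.741, 0.737 and 0.447). let-7i-5p, miR-222-3p and miR-423-5p had log2 changes of 0.15, 0.05 and 0.05 (adjusted p = 0.783, 0.908 and 0.893), each of which turned negative with RLE factors, while without M2 replicate 3 they were 0.65, 0.48 and 0.45 and passed (adjusted p = 0.000546, 0.00462 and 0.00277). The median of all tested miRNAs in that fit was 0.62, so let-7i-5p lay near this shared shift and miR-222-3p and miR-423-5p lay below it. The reads of miR-423-5p were counted equally for miR-3184-3p, which lies opposite it. miR-10b-5p and miR-10a-5p did not pass the test (log2 2.12 and 1.86, adjusted p = 0.344 for each). miR-10b-5p was at 45333 ± 2427 CPM in macrophage exosomes and at 1803, 25408 and 564574 CPM in M2 replicates 1, 2 and 3, and without M2 replicate 3 the log2 changes of miR-10b-5p and miR-10a-5p were -1.61 and -1.51 (adjusted p = 0.198 and 0.105). miR-155-5p, a marker of classical activation, was at 11179 ± 997 and 10345 ± 511 CPM (log2 -0.11 ± 0.17, adjusted p = 0.608). It passed as lower in DESeq2 (log2 -0.64, adjusted p = 0.0270), with a minimum count of 50 (-0.72, 0.0105), in thinned libraries (-1.21, 0.00633) and with the miRNAs raised in M2 replicate 3 left out (-0.49, 0.0464). miR-181a-5p and miR-125a-5p had log2 changes of 1.70 ± 0.76 and 0.58 ± 0.26 (adjusted p = 0.123 and 0.125). miR-181a-5p passed without macrophage replicate 1 (log2 2.79, adjusted p = 0.0152), miR-125a-5p without M2 replicate 3 (0.63, 0.0306), and each in limma-voom with sample weights (0.0276 and 0.0475). Several macrophage or prostate cancer miRNAs chosen beforehand were too scarce to test. miR-223-3p had 4 counts in the macrophage and 42 in the M2 group, miR-95-3p had 15 and 117, of which 109 were in M2 replicate 3, miR-34a-5p had 0 and 30, of which 29 were in M2 replicate 3, and miR-193b-3p had 0 and 1.

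Members of the myeloid identity list, miRNAs typical of monocytes and macrophages, mostly rose. Of 12 tested members 10 rose, 1 fell and 1 did not pass, and 5 of the rises and the fall were called under every scaling. Besides miR-146a-5p, miR-142-3p rose from 421 ± 171 to 2842 ± 437 CPM (SD, n = 3 each; log2 2.75 ± 0.38 SE, edgeR adjusted p = 0.00316), and miR-378a-3p by a log2 of 2.64 ± 0.23 (adjusted p = 0.00100). miR-24-3p rose by a log2 of 2.43 ± 0.43, and its reads were counted also for the antisense miR-3074-5p. The member that fell was miR-223-5p, the passenger arm of miR-223. As a group the list did not pass against the other miRNAs (camera, unadjusted p = 0.0185, adjusted p = 0.231). The miR-142-3p call ended without macrophage replicate 3 (adjusted p = 0.0716) and that of miR-24-3p without macrophage replicate 2 or 3 or M2 replicate 2 (0.0921, 0.0804 and 0.0738).

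Of 10 tested members of the alternative activation list, which holds miRNAs linked to M2 polarisation, 6 rose and 1 fell, 3 rises and the fall under every scaling. The rises included miR-146a-5p and miR-378a-3p, the latter induced by IL-4 in macrophages, and the fall was let-7c-5p. The classical activation list had 3 rises among 10 tested members, miR-27a-3p (log2 1.87 ± 0.33), miR-101-3p (1.65 ± 0.36) and miR-29b-3p, and 1 of them held under every scaling. The list of NF-κB-induced miRNAs had 4 rises among 10, 1 of them under every scaling, among them miR-146b-5p (log2 1.55 ± 0.44) and miR-132-3p (2.18 ± 0.55). The list of TGF-β-induced miRNAs had 5 rises and 1 fall among 16, 2 rises and the fall under every scaling. Its rises included miR-23a-3p (log2 2.77), miR-24-3p and miR-27a-3p, and its fall was miR-183-5p (log2 -1.13 ± 0.26). In the list of miRNAs lowered by TGF-β, 2 of 5 rose, miR-29a-3p (log2 2.09 ± 0.33) and miR-29b-3p, and 1 of them did so under every scaling. Without M2 replicate 3, where 116 of all miRNAs were called, 4 of 5 rose. These changes go against the name of the list. A list of miRNAs published in M2 exosomes had 5 rises among 9, 2 under every scaling, including miR-221-3p and miR-186-5p (log2 2.93 ± 0.28). None of these lists passed as a group (camera adjusted p = 0.241, 0.709, 0.509, 0.709, 0.324 and 0.456 in the order given). Several of the calls ended without 1 library. Without macrophage replicate 3 the adjusted p was 0.122 for miR-27a-3p, 0.240 for miR-101-3p, 0.295 for miR-132-3p, 0.346 for miR-146b-5p and 0.0837 for miR-29a-3p. Without macrophage replicate 2 these became 0.139, 0.199, 0.133, 0.365 and 0.104. Without M2 replicate 2 the values were 0.0899 for miR-27a-3p, 0.138 for miR-101-3p, 0.246 for miR-146b-5p, 0.0702 for miR-29a-3p and 0.0991 for miR-183-5p. Without macrophage replicate 1 miR-132-3p and miR-146b-5p gave 0.0634 and 0.113, and without M2 replicate 1 miR-146b-5p gave 0.0652.

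The let-7 family split. Of 9 tested members, let-7a-5p, let-7b-5p, let-7c-5p and let-7f-5p fell under every scaling, by log2 values of -0.81, -1.89, -1.49 and -0.74, and let-7g-5p rose by 1.48 ± 0.19, a call that ended with total-count scaling (edgeR adjusted p = 0.0905). let-7i-5p and let-7e-5p changed sign between scalings. The family member miR-98-5p did not pass with TMM factors (log2 -0.83, edgeR adjusted p = 0.148). It passed as lower with RLE, upper-quartile and total-count scaling (edgeR adjusted p = 0.0269, 0.0454 and 0.0252) and in DESeq2 (adjusted p = 0.00325). With M2 replicate 3 left out, 5 of 9 members fell and 3 rose. The family members differ by few bases, so reads may have been divided among them in counting. The let-7a-5p call ended without M2 replicate 2 (adjusted p = 0.0954), and that of let-7f-5p without M2 replicate 1 or 2 (0.0601 and 0.0847). That of let-7g-5p ended without macrophage replicate 2 or 3 or M2 replicate 2 (0.118, 0.153 and 0.0673). In the miR-30 family 3 of 5 rose, of which the most abundant, miR-30e-5p, went from 5479 ± 175 to 21245 ± 2990 CPM (SD, n = 3 each; log2 1.95 ± 0.19 SE, adjusted p = 0.00100), and 1 of the 3 held under every scaling. The miR-30e-5p call ended without macrophage replicate 2 or 3 (0.0634 and 0.0556). Without M2 replicate 3, 5 of 5 members of this family rose. In the miR-320 family 3 of 4 rose, miR-320a-3p, miR-320b (log2 2.97 ± 0.54) and miR-320c (2.08 ± 0.57), 2 of them under every scaling. Without M2 replicate 3 the log2 changes of miR-320b and miR-320c were 2.33 and 1.48. Their near-identical sequences leave open how reads were divided, and the miR-320b and miR-320c calls ended without macrophage replicate 2 (0.0673 and 0.236) or 3 (0.0721 and 0.199), that of miR-320c also without macrophage replicate 1 (0.0887) or M2 replicate 2 (0.0641). In the miR-23/27/24 clusters 4 of 7 rose, 1 under every scaling. As groups these families did not pass (camera adjusted p = 0.241 for each of the 4).

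Among miRNAs reported to promote prostate cancer, 3 of 11 rose and 2 fell. miR-21-5p, miR-221-3p and miR-20a-5p rose, and miR-148a-3p and miR-183-5p fell, and 2 of the rises and both falls held under every scaling. The rise that did not hold was that of miR-21-5p, with RLE, upper-quartile and total-count scaling (edgeR adjusted p = 0.244, 0.284 and 0.558) and in DESeq2 (adjusted p = 0.251). The miR-20a-5p and miR-183-5p calls each ended without at least 1 library. Without M2 replicate 3, 5 members of this list rose and 2 fell, with a median log2 change of 0.48 against 0.62 over all tested miRNAs. Among miRNAs reported to restrain it, 5 of 22 rose and 3 fell, 2 rises and the 3 falls under every scaling. The falls were let-7a-5p, let-7b-5p and let-7c-5p, and the rises included miR-146a-5p and miR-16-5p (log2 3.09, called in every alternative in which it was tested). Neither list passed as a group (camera adjusted p = 0.911 and 0.969). For the first, the median (0.68) and mean (0.87) log2 change were positive while camera, which compares with the other miRNAs, placed it lower.

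**Figure D3:**
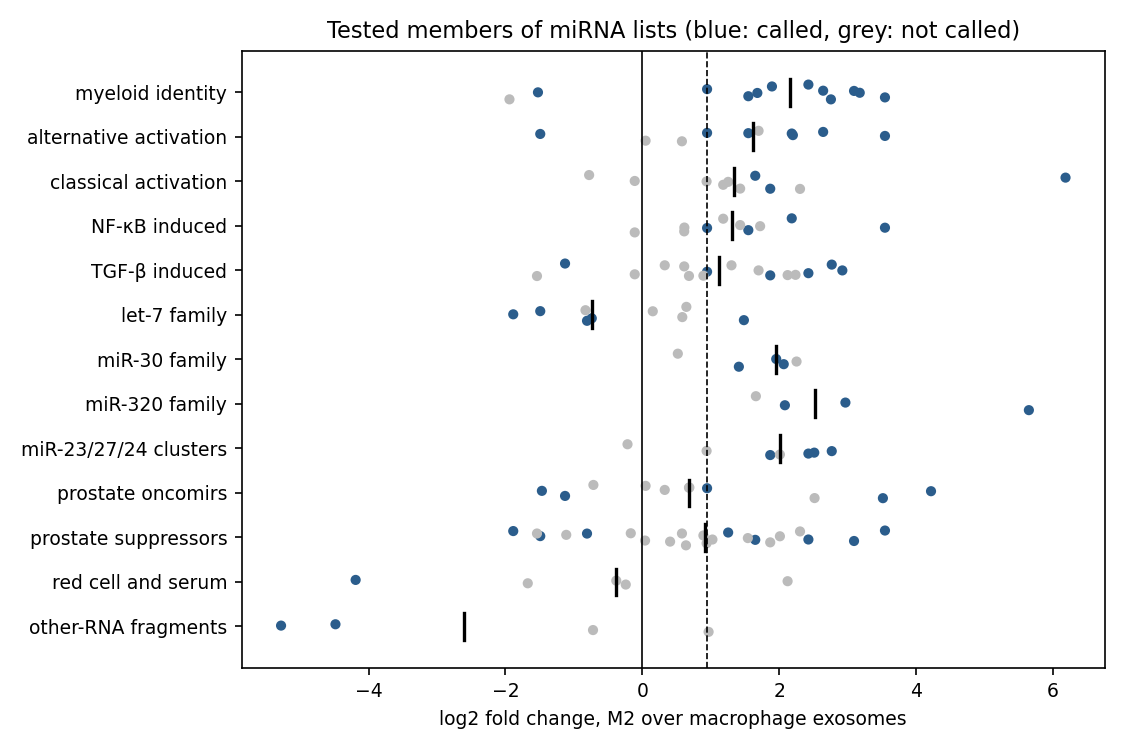
Log2 fold change of M2 over macrophage exosomes for the tested members of 13 miRNA lists, with members of an adjusted p under 0.05 in blue, others in grey and a black bar at each list's median. The dashed line marks the median of all tested miRNAs at 0.95, and 10 of the 12 myeloid identity members are blue and to the right of 0.

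The remaining lists gave these counts. In the families of miR-10, miR-99, miR-100 and miR-125, 2 of 9 rose, miR-99b-3p and miR-99b-5p. The miR-99b-5p call ended under other scalings and without macrophage replicate 2 or 3 or M2 replicate 1 or 2 (edgeR adjusted p = 0.491, 0.552, 0.0613 and 0.298). The median log2 change of these families was 1.54 with all libraries and -0.17 without M2 replicate 3. In the miR-17 clusters 1 of 9 rose (miR-20a-5p), with a positive median log2 change of 1.11 that camera placed below the other miRNAs and that was -0.21 without M2 replicate 3. In the cluster of miR-221 and miR-222 1 of 3 rose (2 of 3 without M2 replicate 3), in the miR-181 family 1 of 3, in the miR-29 family 2 of 2, in the miR-15/16 family 1 of 1 and in the hypoxia list 2 of 3. In the miR-183 cluster 1 of 3 fell and in the 14q32 list 1 of 4, miR-409-3p, with positive medians (0.33 and 0.46) that camera placed below the other miRNAs. Without M2 replicate 3 the 14q32 median was -0.22, with 2 of 6 tested members falling. Of the red cell and serum list, 1 of 5 fell, miR-451a. Its member miR-122-5p did not pass with TMM factors (log2 -1.67, edgeR adjusted p = 0.0742). It passed as lower with RLE, upper-quartile and total-count scaling (edgeR adjusted p = 0.0232, 0.0114 and 0.00735) and in DESeq2 (adjusted p = 0.000957). With M2 replicate 3 left out, 2 of 5 members of this list fell. Among miRNA entries that may derive from fragments of other RNAs, 2 of 4 fell, miR-4488 and miR-4466 (camera unadjusted p = 0.00517, adjusted p = 0.129). Of markers of other cells, 2 of 5 mesenchymal miRNAs (miR-152-3p and miR-199b-5p) and 2 of 6 lymphoid miRNAs rose, 0 and 2 of them under every scaling, while 0 of 1 epithelial, 0 of 2 endothelial and 0 of 6 muscle, neuronal or stem cell miRNAs passed. In the last list miR-129-5p was at 3314, 80.8 and 98.6 CPM in macrophage replicates 1, 2 and 3. Its M2 libraries held 2743, 2492 and 2693 CPM (log2 1.18, edgeR adjusted p = 0.511). It passed without macrophage replicate 1 (log2 4.77, edgeR adjusted p = 0.00524) and in limma-voom with sample weights (3.38, 0.0276). miR-9-3p of that list passed as lower without M2 replicate 3 (log2 -1.91, edgeR adjusted p = 0.0346). The calls of miR-152-3p and miR-199b-5p ended with total counts (edgeR adjusted p = 0.123 and 0.124) and without macrophage replicate 1 (0.0819 and 0.122), 2 (0.246 and 0.133) or 3 (0.323 and 0.402) or M2 replicate 2 (0.168 and 0.146). Those of the lymphoid miR-342-3p and miR-181b-5p ended without macrophage replicate 2 (edgeR adjusted p = 0.200 and 0.123) or 3 (0.125 each). They also ended with macrophage replicates 2 and 3 added up (0.0770 and 0.0700). The mesenchymal list's median log2 change was 2.07 with all libraries and -0.32 without M2 replicate 3. Of the 29 lists 25 had enough members for camera, and 0 passed, with either the preset or an estimated correlation (2 and 1 lists had an unadjusted p under 0.05). Adjusted over the list alone, 4 miR-30 and 4 miR-320 members and 3 TGF-β-lowered miRNAs rose, 2 myeloid members fell, 1 of the miR-10 families rose and 0 of the 14q32 list fell, while every other list kept its counts.

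The hairpins of the named miRNAs lie as follows in GENCODE 29 (GRCh38), as the table itself carries no coordinates. MIR320A lies on chromosome 8 from 22244962 to 22245043, with no gene on its own strand around it. MIR146A lies on chromosome 5 from 160485352 to 160485450, in an exon of the non-coding MIR3142HG. MIR22 lies on chromosome 17 from 1713903 to 1713987, in an exon of MIR22HG. MIR221 lies on chromosome X from 45746157 to 45746266, in an intron of MIR222HG. MIR378A lies on chromosome 5 from 149732825 to 149732890, in an intron of PPARGC1B, and MIR26B on chromosome 2 from 218402646 to 218402722, in an intron of CTDSP1. MIR148A lies on chromosome 7 from 25949919 to 25949986, with no gene on its own strand around it, and MIRLET7B on chromosome 22 from 46113686 to 46113768, in an exon of MIRLET7BHG. MIR451A lies on chromosome 17 from 28861369 to 28861440, in an exon of a long non-coding RNA, and MIR4488 on chromosome 11 from 61508596 to 61508657, outside any gene of its strand.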

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

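The rule for scarce miRNAs, and the tests on M2 replicate 3 other than thinning, were chosen after the counts had been seen. Of the 475 miRNAs left out by the count filter, 291 had no count in any macrophage library, and 6 of these had 10 or more counts in every M2 library, a signal outside the main test and above the limit that a count of 0 allows. miR-210-3p, a hypoxia-induced miRNA, was at least 31.8-fold higher in M2 exosomes against 3 counts over the macrophage group (11, 22 and 123 counts). By the same measure miR-147b-3p was at least 18.5-fold higher, miR-12136 at least 16.9-fold, miR-23a-5p at least 13.0-fold, miR-576-3p at least 10.2-fold and miR-4485-3p at least 9.78-fold. With total counts alone (206493 in the macrophage and 613333 in the M2 group) the bounds were 17.5-fold for miR-210-3p, 10.2-fold for miR-147b-3p, 9.31-fold for miR-12136, 7.18-fold for miR-23a-5p, 5.61-fold for miR-576-3p and 5.39-fold for miR-4485-3p. Without M2 replicate 3 the bounds of miR-210-3p and miR-12136 fell to 14.2-fold and 10.8-fold. All these bounds leave out the counting error of the M2 counts. Of the 6, miR-12136 and miR-4485-3p are also on the list of entries that may derive from fragments of other RNAs. In the edgeR fit without a filter they had log2 changes of 7.17 and 6.85, while camera placed that list lower. The edgeR fit without a filter called 35 of the 475, 26 higher, with these 6 among them, and 9 lower, such as miR-184 with 7, 68 and 62 counts in macrophage and 7, 4 and 7 in M2 replicates 1, 2 and 3 (log2 -3.91, adjusted p = 2.9e-05). Macrophage replicate 1 held as few counts of miR-184 as M2 replicate 1. Its fall therefore rests mainly on macrophage replicates 2 and 3, which lay close to sampling noise of each other.

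M2 replicate 3 stood apart from M2 replicates 1 and 2, with 16 miRNAs at least 8-fold higher, among them miR-10b-5p, miR-10a-5p, miR-99a-5p, miR-218-5p and miR-9-3p, which together took 39.6% of its counts, against 0.427% and 3.25% in M2 replicates 1 and 2 and 8.23%, 8.46% and 8.63% in macrophage replicates 1, 2 and 3. The tables argue against depth, since with every library thinned to 56199 counts its median distance from the other M2 libraries was still 2.66 times theirs from each other. The red cell and serum list (5 tested members) rose in it by a median log2 of 0.43, against 5.37 for miR-10b-5p. That median is the value of miR-486-5p and miR-486-3p, which share reads. With miR-451a at -0.01, these values argue against red cell RNA as the whole cause. miR-122-5p (2.00) and miR-363-3p (3.99) rose more, so serum RNA is left open. miR-363-3p is also counted among the markers of other cells below. The tables also argue against a macrophage library under the wrong label. The median log2 difference of M2 replicate 3 from the macrophage mean was greater by 3.26 over the miRNAs called higher without it than over those called lower. In the left-out macrophage libraries this value was at most 0.15. The spread of the 2 sets, from their interquartile ranges, was 2.46, and 3.26 less that spread was asked to stay above 0.15. An earlier test that this one replaced had left the question open, with 65.5% of the miRNAs called without M2 replicate 3 on the M2 side of the midpoint where 75% was asked. A mixture of both kinds of exosome was not tested. RNA of other cells is a candidate explanation, since 18 tested markers of such cells rose in it by a median log2 of 1.37, at percentile 98.9 of 10000 matched random lists, with the largest for miR-9-3p (4.51), miR-199a-3p (4.06) and miR-363-3p (3.99), which are also among the 16, while miR-126-3p (-1.51), miR-342-5p (-1.32) and miR-28-5p (-0.08) were lower. Whether 1 source was added to every library cannot be told apart: the interquartile range of the set's log2 ratio to the macrophage level (0.984) was as small in 0.11% of random lists (median 3.03), but the set was chosen on M2 replicate 3 itself, and the 4 miRNAs lowered 8-fold, chosen in the mirrored way, had a range of 0.984 too.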

How the results depend on the processing

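Of the 55 named miRNAs that were called, 17 kept the call under every alternative that tested them, and 20 under every replicate left out. The cause of the changes below was not tested unless stated. Antisense partners left out, macrophage replicates 2 and 3 added up, thinning for the calls, sample weights, the raised set left out and the estimated correlation without a filter were chosen after seeing the data. Against 70 differing miRNAs and 66 of at least 2-fold, leaving out each replicate gave 35 to 116 and 35 to 95, adding up macrophage replicates 2 and 3 gave 38 and 38, which has 1 library fewer, and sample weights in limma-voom gave 118 and 102, with the lowest weight for M2 replicate 3 (0.0886). A threshold of 0.01 gave 34. With the replicate block the counts were 40 and 40, and 22 named calls ended, such as those of miR-1269b (adjusted p = 0.0661), miR-6515-5p (0.0790) and miR-223-5p (0.0888). The replicate numbers did not pair the samples, as the deviations of same-numbered libraries correlated at 0.0970, 0.00391 and 0.0207, and only number 1 correlated best with its own number. RLE, upper-quartile, total counts, DESeq2, limma-voom, limma-trend, no filter, a minimum of 50, the 5 most abundant or antisense partners left out, thinning, the raised set left out and a threshold of 0.1 gave counts within 1.5 times. Without a filter 7 lists passed, against 0: myeloid identity, alternative activation, let-7, miR-320, miR-23/27/24, hypoxia and RNA fragments, but 0 with the correlation estimated per list (smallest adjusted p 0.594). Every replicate left out gave 0 lists. miR-21-5p reversed to a log2 change of -0.11 in thinned libraries (adjusted p = 0.811, range over alternatives 7.24e-05 to 0.811), and miR-9-3p to -1.91 without M2 replicate 3 (0.0346, range 0.0346 to 0.992; the highest log2 change was 1.85, without M2 replicate 1). The M2 minus macrophage difference in the share of the 10 most abundant (1.96 percentage points) was 8.44 for the most abundant alone and -1.12 for the 50 most abundant, and -1.63 to 3.90 with a replicate left out, the lowest without M2 replicate 3. The difference in miRNAs detected (68.3) was 127 at 1 count, 2.67 after thinning, so that most of it went with depth, and 38.7 to 87.7 with a replicate left out. In simulations with the depths and spread of these libraries 2-fold changes were mostly missed.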

Other observations

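The tests of the 2 arms of a hairpin were set before their result was seen, while the test on normalization factors and the choice of the miRNAs nearly unread in macrophage replicates 2 and 3 came after. In M2 exosomes miR-30e-5p rose (log2 1.95) while miR-30e-3p fell (-0.92, edgeR adjusted p = 0.0144), from 5577 ± 443 to 2948 ± 319 CPM (SD, n = 3 each). let-7d-3p fell by a log2 of -2.89 with let-7d-5p at 0.64 (adjusted p = 0.229), and miR-221-3p rose by 3.51 with miR-221-5p at 0.40 (0.418). Of 20 hairpins with both arms tested, 8 differed between arms within the hairpin (edgeR diffSpliceDGE, adjusted p under 0.05), namely miR-30e, let-7d and miR-340 with the greater log2 change in the 5p arm and miR-221, miR-99b, miR-22, miR-342 and miR-27a with the greater log2 change in the 3p arm. Library scaling cancels within a hairpin, so the 8 argue against it as the whole cause, and all 8 passed in the same direction without M2 replicate 3, against that library alone. In simulations of 20 hairpins with independently drawn arms, the test called 7.6 of 10 hairpins raised 8-fold, as a mean over 10 draws. It made 0.8 wrong calls per draw, against 0.2 in unchanged data, so some of the 8 may be wrong. No library other than M2 replicate 3 was left out of the arm test. The single calls of miR-30e-5p, miR-342-3p and miR-27a-3p ended without macrophage replicate 2 or 3. A difference between groups in how arms are kept or sorted into exosomes is a hypothesis that was not tested here.

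Rises outnumbered falls with TMM factors (72.9% of the calls), but the choice of factors is a candidate explanation for that balance, as the share of rises was 49.1% with total counts alone. The fall of 19 and the rise of 28 miRNAs did not depend on that choice.

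The division into macrophage and M2 exosomes gave 70 differing miRNAs, and the highest count among the other splits of the 6 libraries was 0. With 1 of 10 splits reaching that count, the splits are too few for a share under 0.05.

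A further 6 miRNAs had 10 or more counts in macrophage replicate 1 and every M2 library but no more than 2 counts in macrophage replicates 2 and 3 together. miR-127-3p had 383, 0 and 1 counts in macrophage replicates 1, 2 and 3, and 418, 379 and 541 in M2 replicates 1, 2 and 3. The others were miR-433-3p, miR-584-5p, miR-200b-3p, miR-133a-3p and miR-139-3p. Together they had 496, 2 and 2 counts in the macrophage libraries and 513, 457 and 737 in the M2 libraries. No miRNA met the mirrored rule for macrophage replicate 2 or for replicate 3. No explanation of this was tested.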
